A study of Arabidopsis thaliana with 16 samples.

How the data were processed

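Total RNA of wild-type Arabidopsis thaliana of the ecotype Landsberg was measured on arrays after 48 hours in white light or in blue light, both at 20 µE, per the labels. Each light condition had 8 samples, numbered 1 to 8. The organ and the age of the plants are not given in the sources used here, and nothing in the labels states whether the samples came from separate plants.

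The deposited values were linear intensities for 3439 features in 16 columns, with no value below 0 and a highest value of 100. The authors' background correction, scaling and image processing are not given in the sources used here. In 9 columns the highest intensity was 100, and between 11.7% and 16.7% of the features of a column were listed at exactly 0. The medians of the columns spanned 2.66 on the log2 scale, so the deposited intensities had not been brought to a common level. What the scale refers to stays unknown, and each change below is a change relative to the other features on the same arrays.

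Genes were named through the platform annotation, which can be old, with symbols updated through the TAIR10.1 gene table. Exactly 1 gene was paired with 692 features, several genes with 870 and none with 1877. Of the single-gene features, 690 were matched to the gene table. Only single-gene features are named, and no coordinates are given because the build of the annotation is not given in the sources used here.

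Values were put on the log2 scale with entries of 0 treated as missing. A feature was tested if it was above 0 in at least 6 of the 8 columns of each group, which left 2864 features. A rule set before the data were examined called for quantile normalization if the column medians spanned more than 0.2, and it was applied.

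The fit set before the data were examined used all 16 columns as separate samples. It was not kept as the main result. In each of the 16 columns, the closest other column was the one with the neighbouring replicate number (1 with 2, 3 with 4, 5 with 6, 7 with 8). The SD between such neighbours was 0.42 on the log2 scale, against 0.64 between their averages within a light group. The labels do not say what the neighbours share, and repeat readings of 1 array would look like this. Neighbours were therefore averaged and counted as 1 sample, which gave 4 averaged samples per group, called samples 1 to 4. This was decided after the data were seen, and the counts from 16 columns are given beside the main ones. If the neighbours are separate samples after all, the main counts are too low.

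Blue light was compared with white light with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. All adjusted p-values are from limma unless another test is named. The p-values measure the spread between the averaged samples, which may be technical. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, for lists with at least 3 tested members. Values of whole arrays were compared by exact permutation tests, two-sided, whose smallest possible p with 4 against 4 is 0.0286.

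The same-numbered averaged samples of white and blue light deviated together from their group means, with correlations across features of 0.38, 0.45, 0.18 and 0.34. Each of the 8 averaged samples correlated best with its own number in the other group. Between samples of different numbers the correlations ran from -0.25 to 0.104. The limit for pairing was a correlation of 0.1 in every pair, so the numbers were taken to pair the samples. The fit set before the data were examined had no covariate, and the main fit was kept without a block. The fit with this pairing as a block was an alternative, so the main values and calls do not use the pairing.

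The genes named were chosen by a rule set before the data were examined: the 6 single-gene features with the largest change past the threshold in each direction, and up to 2 members per direction of each of 22 gene lists. A further 13 genes were to be named whatever their result, and none of them had a single-gene feature. The other tested members of the lists are given too, chosen because so few were measured. Another 6 lists were written from gene names after the data were seen, when the values of a few members were already known.

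Alternatives covered the normalization, low values, dim features, the replicate block, the variance model, the test, the threshold and each sample left out. Low values were handled at the 10th percentile of the values above 0, because the percentile over all values was 0, and this gave a pseudocount of 0.109. The preset fit of 16 separate columns was run beside them. Added after the data were seen were the averaged sample as a random block, each averaged sample left out and replicates 7 and 8 of both groups left out. Cyclic loess, subtraction of a local median over 25 consecutive feature numbers and scaling to total signal were added then too. So was an exact test of array medians within the number pairs.

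The steps were tested on simulated data for the same comparison, with 10 runs on 2864 features of which 200 changed. The first version of this test mixed 2-fold and 3-fold changes, of which 3.0% and 23.1% were found, with 2.0 false calls per run. It counted part of the reading noise in duplicate. A second version, written after that result was seen, took this part off and found 13.4% and 54.9% of the same changes, with 4.0 false calls. With 2-fold, 4-fold and 8-fold changes mixed, the second version found 18.5%, 78.9% and 93.5%, with 8.4 false calls per run, and the first noise setting found 8.97%, 73.3% and 92.6%, with 6.9. With no change simulated, the averaged samples gave 0 calls under both noise settings, while 16 separate columns gave 19.4 per run under the first and 12.7 under the second. These simulated counts cannot show whether neighbouring columns of the real data are separate samples. Changes of 2-fold were thus mostly missed in these simulations. In the real data 32.4% of the tested features passed, a larger share than the 200 of 2864 simulated. The adjusted threshold depends on that share, so the shares found may differ in the real comparison. A rule for reading the effect of total signal was also made stricter after its value was seen, by asking that the value pass its bound by more than its standard error.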

Results

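Transcript levels were compared between wild-type Landsberg plants kept for 48 hours in blue light and plants kept for 48 hours in white light, both at 20 µE. The question set by the labels was how blue light differs from white light at the same fluence rate. Each light group had 8 array columns. Columns with neighbouring replicate numbers were averaged and counted as 1 sample, because each column was closest to its neighbour, so n = 4 averaged samples per group. Total signal per column ran from 1044 to 3320 units in white light and from 3067 to 3735 in blue light. The number of arrays limits the precision of every value.

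In blue light, 456 features were higher and 471 were lower than in white light, out of 2864 tested. This fit did not use the pairing by number, and with that pairing as a block the counts were 596 and 599. Among single-gene features the largest rise after quantile normalization was that of AT5G53930, by 3.34 on the log2 scale (SE 0.59, n = 4 per group). AT1G78620, which encodes the phytyl phosphate kinase VTE6 of tocopherol synthesis, rose by 3.30 (SE 0.45). The largest falls among single-gene features were those of AT3G56010, which fell by 3.75 (SE 0.75), and AT5G52810, which fell by 3.62 (SE 0.44) and encodes SARD4, an enzyme of pipecolic acid synthesis. Of the 12 genes with the largest changes, 7 were among the 25% of tested features with the lowest mean level, AT5G53930 and AT3G56010 included, so the order of these changes is uncertain. Among photosynthesis genes, PSBW, a small subunit of photosystem II, rose by 2.13 (SE 0.28), and PRK, the phosphoribulokinase of the Calvin cycle, fell by 0.91 (SE 0.29). Neither call held under every scaling. PSBW was at 0.63 with median centring and PRK at 0.48 without normalization, and neither value passed.

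Among the other large rises, AT1G44830, a transcription factor of the ERF/DREB family, rose by 2.87 (SE 0.51, limma adjusted p = 0.00258). AT4G17070 rose by 2.81 (SE 0.32, adjusted p = 0.000339) and AT1G08845 by 2.80 (SE 0.41, adjusted p = 0.00108). The adjusted p was 0.00254 for AT5G53930 and 0.000652 for AT1G78620. With median centring the log2 change of AT4G17070 was 1.64. With the pseudocount the log2 change of AT1G08845 was 1.85 and the log2 change of AT1G44830 was 1.76, against 4.23 and 4.35 without normalization. The log2 change of AT5G53930 was 1.83 with low values raised to the 10th percentile and 1.39 with the pseudocount, where the log2 change of AT1G78620 was larger, at 3.15 and 2.60. AT5G53930 did not pass with the averaged sample as a random block (SE 1.87, adjusted p = 0.188). AT3G60590 rose by 3.08 (SE 0.88, adjusted p = 0.0224). It rose by 2.02 without white light replicates 7 and 8, and also by 2.02 without white light replicate 7 alone. White light sample 4 was at -8.27, against -2.95, -4.58 and -4.65 in the others, and appears to rest on replicate 7 alone. Part of the rise thus depends on a low reading in a gene among the 25% of lowest mean level. The call of AT3G60590 ended without blue light replicates 1 and 2 (3.04), 3 and 4 (3.03) or 5 and 6 (3.02). With low values raised to the 10th percentile it rose by 1.22, with the pseudocount by slightly less and without normalization by 4.62, and by an unmoderated two-sample test it did not pass (adjusted p = 0.0976).

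Among the other large falls, AT3G07790, a DGCR14-related gene, fell by 3.42 (SE 0.29, adjusted p = 9.9e-05). AT4G02580, which encodes the 24 kDa subunit of mitochondrial complex I, fell by 3.37 (SE 0.53, adjusted p = 0.00132). AT5G36470 fell by 3.15 (SE 0.31, adjusted p = 0.000218), and AT4G15840, a BTB/POZ domain gene, fell by 2.95 (SE 0.32, adjusted p = 0.000349). The adjusted p was 0.00486 for AT3G56010 and 0.000407 for AT5G52810. With low values raised to the 10th percentile, the changes of AT3G56010 (-0.48, adjusted p = 0.178) and AT4G02580 (-0.70, adjusted p = 0.153) did not pass, and AT3G56010 did not pass with cyclic loess either (-2.04, adjusted p = 0.0538). Without normalization AT4G15840 did not pass (-1.22, adjusted p = 0.0569), and with a local median subtracted the log2 change of AT4G15840 was -1.82. Without normalization the log2 change of AT3G07790 was -1.94, the log2 change of AT5G36470 was -1.91, the log2 change of AT3G56010 was -1.76 and the log2 change of AT4G02580 was -1.47. With the pseudocount the changes of AT3G07790, AT3G56010 and AT4G02580 were -2.25, -0.99 and -1.06. Scaled to total signal AT3G56010 was at -2.46 and AT4G02580 at -2.17, and AT4G02580 was at -2.16 with cyclic loess.

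**Figure D1:**
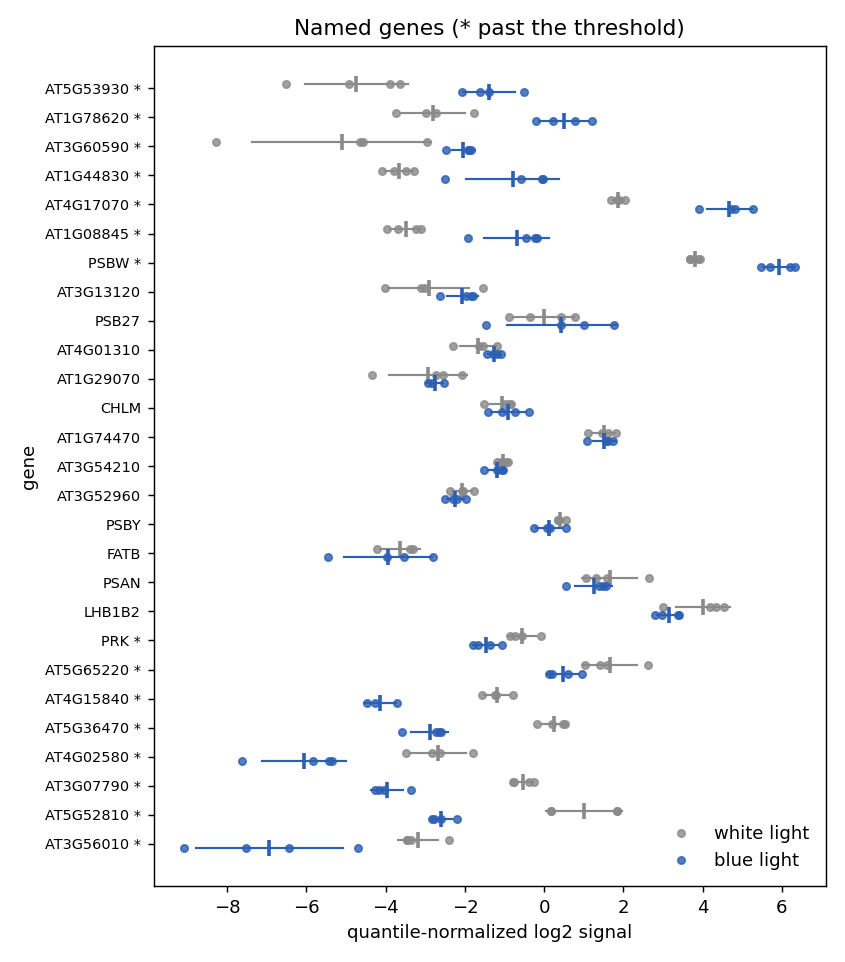
Quantile-normalized log2 signal of 27 named genes, with 1 point per averaged sample (n = 4 per group, fewer where a value was 0), a tick at the mean and a line of 1 SD to each side. Genes past the threshold carry a star, and PSBW lies higher in all 4 blue light samples than in any white light sample.

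Of the 360 genes in the 22 lists, 17 had a single-gene feature and 15 could be tested. Of these, 1 rose, 2 fell and 12 did not pass, and the same count of 3 passed when adjusted over the lists alone. Over all tested single-gene features 30.7% passed, so a few passing members say little about a list. Lists with no tested member numbered 14, among them the photoreceptors, flavonoid synthesis, the clock, the control genes and the root, seed, flower and senescence markers.

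Of the photosystem II subunits, 1 of 3 tested members rose and none fell. PSBW passed with an adjusted p of 0.00058, while PSBY (-0.27) and PSB27 (0.44) did not pass. The list as a whole did not pass (camera adjusted p = 0.575, and adjusted p = 0.961 with an estimated correlation). With median centring, the change of PSBW was 0.63 and did not pass (adjusted p = 0.105), and scaled to total signal it was 1.42 and passed. With median centring PSBY passed at -0.88. PSBY also passed with a local median subtracted (-0.89). PSAN of photosystem I changed by -0.41 and did not pass (-1.43 with median centring, which passed).

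LHB1B2, a chlorophyll-binding protein of the light-harvesting antenna, changed by -0.86 (SE 0.36, adjusted p = 0.0925) and did not pass. With the replicate block its adjusted p was 0.0402, and over its alternatives the adjusted p ran from 0.00269 to 0.315. It passed with median centring (-2.27), scaled to total signal (-1.49), with a local median subtracted (-1.16) and with 16 separate columns. It also passed without white light replicate 7 (-0.97), without white light replicates 7 and 8 (-1.20) and without replicates 7 and 8 of both groups (-1.09).

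In the Calvin cycle list, PRK was the single member tested and had an adjusted p of 0.0348. Without normalization its change was 0.48, in the other direction, and scaled to total signal it was -0.22, and neither passed. Its call also ended without blue light replicate 7 (-0.84), blue light replicates 1 and 2 (-0.84), 3 and 4 (-0.94) or 5 and 6 (-0.80), and without white light replicates 3 and 4 (-0.91), 5 and 6 (-0.97) or 7 and 8 (-0.75).

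Of the plastid ribosomal proteins, 1 of 5 tested members fell and none rose. AT5G65220, which encodes protein L29, fell by 1.19 (SE 0.37, adjusted p = 0.0315). AT3G13120 (0.85), AT4G01310 (0.42), AT3G54210 (-0.15) and AT1G29070 (0.16) did not pass. The list did not pass (camera adjusted p = 0.955 on 4 members, and adjusted p = 0.961 with an estimated correlation). The call of AT5G65220 ended without normalization (-0.58), with low values raised to the 10th percentile (-1.21, adjusted p = 0.0521) and by the unmoderated two-sample test (adjusted p = 0.0707), and its change was -2.06 with median centring. The call also ended without white light replicates 1 and 2 (-1.22) or 3 and 4 (-0.88), and without blue light replicates 1 and 2 (-1.10), 3 and 4 (-1.24) or 7 and 8 (-1.08). AT3G13120 passed without white light replicates 7 and 8 (1.32), without replicates 7 and 8 of both groups (adjusted p = 0.00891) and scaled to total signal (1.73), AT4G01310 passed scaled to total signal (1.21), and AT3G54210 passed with a local median subtracted (-0.90).

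In chlorophyll synthesis neither tested member passed, CHLM at 0.16 and AT1G74470, the geranylgeranyl reductase gene, at 0.00. The antioxidant enzyme gene AT3G52960, a plastid peroxiredoxin, changed by -0.17 and FATB, a plastid acyl thioesterase, by -0.29, and neither passed. With the replicate block FATB was at 0.21, in the other direction. Without normalization AT3G52960 (1.37), CHLM (1.52), AT3G54210 (1.29), AT1G29070 (1.86), AT4G01310 (1.91) and AT3G13120 (2.43) all passed as higher, and with median centring AT1G74470 passed as lower (-1.02).

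A few genes were listed at 0 on all columns of 1 light group. Chosen after their values were seen, AT2G21530 was listed at 0 on all 8 white light columns and had a signal of 0.560 ± 0.269 (SD) on all 8 blue light columns, and AT4G01810 was listed at 0 on all white light columns and above 0 on all 8 blue light columns. AT3G49740, a pentatricopeptide repeat gene, was listed at 0 on all 8 blue light columns with a signal of 0.370 ± 0.234 on the 8 white light columns. In all, of 3439 features, 19 were listed at 0 throughout white light and above 0 on at least 6 blue light columns, and 7 the other way. The deposited median was lower in white light, so the larger count there may follow from the lower signal alone. A listing of 0 can be a failed estimate, so no fold is given.

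Over all tested features, 927 passed (32.4%), of which 49.2% were higher in blue light, and 410 rose and 399 fell by at least 2-fold. The groups did not overlap for 953 features (33.3%), where chance gives 2.86% if all averaged samples exchange freely. That share takes no account of the pairing by number. Treating the 16 columns as separate samples, as set before the data were examined, gave 734 higher and 749 lower. The exact rank-sum test on the averaged samples cannot go below p = 0.0286 and gave 0 calls after adjustment, with 916 features at an unadjusted p below 0.05, against 1232 by limma.

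**Figure D2:**
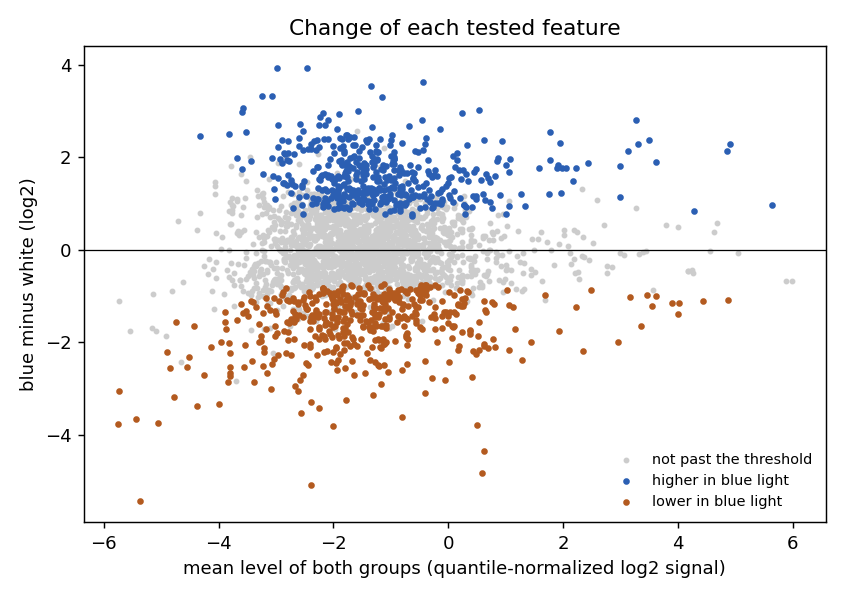
Log2 change (blue minus white) of the 2864 tested features against their mean quantile-normalized log2 level, with 1 point per feature. The 456 features higher in blue light and the 471 lower ones lie across the range of levels.

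The balance of higher and lower features depended on the scaling. As deposited, 1530 features were higher and 44 lower in blue light (97.2% higher). Scaled to total signal, the counts were 1074 and 213 (83.4% higher), and with median centring 380 and 554 (40.7% higher). These scalings moved the median change of all features by 1.36, 0.67 and -0.12.

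The median signal as deposited was itself higher in blue light, at -0.66 ± 0.26 (SD, n = 4) against -2.17 ± 0.70 in white light on the log2 scale. The difference of 1.51 had an exact permutation p of 0.0286, the smallest possible when all samples are exchanged freely. Blue light was higher within each of the 4 number pairs (by 1.07 to 2.12), but exchanging labels only within these pairs gave an exact permutation p of 0.125, which is the smallest that 4 pairs allow and does not pass. The number of features at 0 was 444 in blue light and 482 in white light (exact permutation p = 0.343). The spread of log2 signal across features as deposited also differed, with an SD of 1.41 ± 0.07 in blue light and 1.72 ± 0.10 in white light. Its exact permutation p was 0.0286 with free exchange and 0.125 within the number pairs. Quantile normalization brings the columns to the same spread, while median centring leaves this difference in place.

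**Figure D3:**
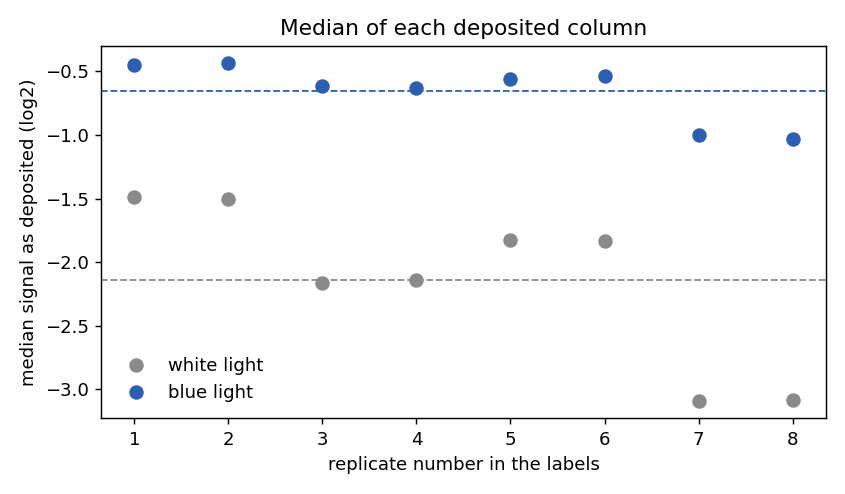
Median log2 signal as deposited of each of the 16 columns against its replicate number, with 1 point per column and a dashed line at each group's mean. All 8 blue light medians lie above all 8 white light medians, and neighbouring numbers lie close together.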

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

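Of 81 groups of 4 averaged samples examined, 7 held a sample far from the others, and chance gives about 5% of groups. The test of exchanged labels was chosen after the result was seen, as were cyclic loess, the local median and scaling to total signal as settings. AT3G56010 in white light had sample 3 at -2.41, with the others between -3.47 and -3.36. PSBY in white light had sample 4 at 0.54, with the others between 0.35 and 0.36. AT3G60590 had blue light sample 4 at -2.47 and AT1G08845 had it at -1.93, both below the other blue light samples. AT5G36470 had blue light sample 3 at -3.59 and PSAN had it at 0.55, again below the others. Blue light sample 4 had 485.5 features at 0, against 425.5 to 434 in the others.

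The number of features that differed between the light groups was weighed first. Among the 35 splits of the 8 averaged samples into 4 and 4, 1 gave as many as 927 features, the real split, and the highest other split gave 0. Chance can be excluded on that count only if the samples are exchangeable across numbers. The numbers were taken to pair the samples, and the 8 splits that part all 4 number pairs, of which the other 7 gave 0, are too few for a share under 5%. With cyclic loess 873 features passed, among them 817 of the 927, so most calls remained under either normalization. Fewer of the 927 were kept in the same direction as deposited (497) or scaled to total signal (645). Quantile normalization and loess both adjust for differences with level, so loess was no independent test of level-dependent scaling. With a local median over 25 consecutive feature numbers subtracted, 1111 passed, among them 776 of the 927. Whether feature numbers follow position on the array was not established, so this step cannot decide on spot position. A response to the light treatment is a hypothesis that may account for the pattern, and growth or handling that differed with the light group stays open, since no table separates it from the light.

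The higher deposited median in blue light was weighed next. Over features above 0 in all 16 columns the difference was 1.49, so more spots above 0 in blue light do not account for it. Dividing each column by its total signal left 0.81 (SE 0.09), above the bound of 0.76 by less than its standard error. The total is the sum of the same features, so a shift of most features would raise it too and the division would shrink the gap whatever the cause. A difference in totals and a true shift cannot be told apart here.

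White light replicates 7 and 8 stood apart, with a total signal near 1044 each. Their mean rank correlation was higher with the other white light samples than with blue light samples of other numbers, by 0.26, which argues against an exchanged label. The rule for reading this comparison was written after the data were seen. Among the brightest 25% of features their mean rank correlation with the other white light samples was 0.64, against 0.84 among those samples, so dim signal near background is not the whole cause. The rank correlation of white light sample 4 with blue light sample 4 was 0.61, against a mean of 0.44 with blue light samples of other numbers. Blue light replicates 7 and 8 also had the lowest total signal of their group, at 3096 and 3067. The standing apart may thus not be particular to white light. No biological explanation was tested for white light sample 4.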

How the results depend on the processing

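Scaling to total signal, cyclic loess, the local median, the random block, the omission of whole averaged samples or of replicates 7 and 8 of both groups, and the test of medians within number pairs were settings chosen after the data were seen, while the 16 separate columns were the preset fit. The counts of 456 higher and 471 lower features stayed within 1.5 times under 12 of 17 alternatives. They became 1530 and 44 without normalization, 1074 and 213 scaled to total signal, 0 and 0 by the exact rank-sum test (too few samples to pass), 209 and 249 at an adjusted p below 0.01, and 734 and 749 with 16 separate columns. With the replicate block they were 596 and 599, and the block brought LHB1B2, AT1G31790 and AGL26 past the threshold and changed no other call among the 39 genes run under it. The unmoderated two-sample test ended 6 of their calls and the averaged sample as a random block ended 4. With samples left out they ran from 317 to 499 and from 329 to 491, and without replicates 7 and 8 of both groups they were 542 and 551. No feature called in the main comparison was called in the other direction under these settings. Of the 927 calls, 497 were kept without normalization and 645 scaled to total signal. The difference in array medians was 0.03 after quantile normalization, 1.51 as deposited, 0.81 scaled to total signal and 1.48 as deposited with 16 columns. Without normalization, which moved the median of all features by 1.36, the called falls of PRK (0.48) and GH9B12 (0.41) turned in sign, as did the uncalled changes of AT3G54210 (1.29), AT3G52960 (1.37), PSBY (0.61), PSAN (0.05) and FATB (1.01). Uncalled changes turned under other settings too, and none of the following passed. FATB was at 0.21 with the replicate block, 0.03 with low values raised and 0.07 with the pseudocount. AT1G29070 was at -0.37 with low values raised and -0.45 with the pseudocount, and PSB27 was at -0.21 with median centring. AT1G74470, at 0.00 and so with no direction to turn, was at -1.02 with median centring and passed. The turns without normalization came with a shift of all features and say little about single genes relative to the others. Whether that shift is real was not settled, so the direction of these genes in absolute level stays open. With median centring the median change of all features was only -0.12, so such a shift does not account for the value of AT1G74470. Median centring leaves in place the wider spread in white light (SD 1.72 against 1.41 in blue light). Bright named genes were lower with it than after quantile normalization, such as PSBW (0.63 against 2.13), LHB1B2 (-2.27 against -0.86) and AT3G26630 (-2.23 against -0.98). AT1G74470 moved the same way, so its value says little about this gene alone. Other causes were not tested. The photosystem II and plastid ribosomal lists passed under no alternative run. With the 25% of features of lowest mean level left out, 411 were higher and 365 lower of 2148, and 727 of the 927 calls were kept, and the 28 named genes still tested stayed on the same side of the threshold. Signal over background is not given in the sources used here.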

Other observations

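The lists in this part were written from gene names after the data were seen. Their counts stand beside a share of 30.7% passing over all tested single-gene features. Of the pentatricopeptide repeat proteins, which bind organelle RNA, 3 of 14 tested members rose, 2 fell and 9 did not pass. AT4G04370 rose by 2.14 (SE 0.31), AT2G46050 by 1.89 (SE 0.30) and AT4G21170 by 1.49 (SE 0.32), while AT5G15280 fell by 1.51 (SE 0.42) and AT3G26630 fell by 0.98 (SE 0.24). AT1G31790 changed by 0.95 and did not pass (adjusted p = 0.0548), but passed as higher with the replicate block (adjusted p = 0.0140), which makes 4 members higher and 8 not past. Named after its values were seen, it also passed without normalization (2.51), scaled to total signal (1.81), with a local median subtracted (1.02) and with 16 separate columns. It passed too without white light replicate 1 (0.99), 4 (1.01) or 8 (0.99), blue light replicate 7 (1.01), white light replicates 1 and 2 (adjusted p = 0.0474) or 7 and 8 (1.06), or blue light replicates 5 and 6 (1.13). The list did not pass (limma camera adjusted p = 0.666, and adjusted p = 0.802 with an estimated correlation). Without normalization neither fall passed (-0.16 and -0.74), and with median centring AT4G21170 did not (0.87). The log2 change of AT4G04370 without normalization was 3.47, the log2 change of AT2G46050 3.32 and the log2 change of AT4G21170 2.35. The call of AT5G15280 also ended without white light replicate 8 (-1.14), white light replicates 3 and 4 (-1.29) or blue light replicates 5 and 6 (-1.35), scaled to total signal (-0.86), by the unmoderated two-sample test (adjusted p = 0.0613) and with the averaged sample as a random block (adjusted p = 0.128). The call of AT3G26630 ended without white light replicate 8 (-0.70) and with the averaged sample as a random block (adjusted p = 0.174), and its change was -2.23 with median centring.

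Among the AGAMOUS-like genes, AGL54 rose by 2.44 (SE 0.40) and the other 2 members did not pass without the replicate block (camera adjusted p = 0.353, and adjusted p = 0.708 with an estimated correlation). With the replicate block AGL26 (0.67, adjusted p = 0.254) passed as higher (adjusted p = 0.0443). Named after its values were seen, it also passed without normalization (2.09), scaled to total signal (1.39) and with a local median subtracted (0.75). The log2 change of AGL54 was 3.88 without normalization and 1.62 with the pseudocount. In the glycosyl hydrolase family 9 class B, GH9B16 rose by 1.48 (SE 0.30) and GH9B12 fell by 1.06 (SE 0.34), with a camera adjusted p of 0.766 and an adjusted p of 0.899 with an estimated correlation. The log2 change of GH9B16 was 2.95 without normalization and 2.25 scaled to total signal. GH9B12 did not pass scaled to total signal (-0.29), and its direction turned without normalization (0.41). Its call ended without blue light replicates 1 and 2 (-0.97) or 3 and 4 (-1.01), and without white light replicates 3 and 4 (-0.96) or 7 and 8 (-0.84). It ended too without replicates 7 and 8 of both groups (-0.88) and by the unmoderated two-sample test (adjusted p = 0.0652).

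Of the mTERF family, which acts in organelle gene expression, 1 of 6 tested members rose, AT1G79220 by 1.28 (SE 0.36), with a camera adjusted p of 0.353 and an adjusted p of 0.708 with an estimated correlation. Its call ended without blue light replicate 7 (1.15), blue light replicates 3 and 4 (1.11) or 5 and 6 (1.12), and white light replicates 5 and 6 (1.18). It ended too by the unmoderated two-sample test (adjusted p = 0.0508) and with the averaged sample as a random block (adjusted p = 0.0627). The log2 change of AT1G79220 was 2.69 without normalization and 1.99 scaled to total signal. Of the histone H3 genes, 1 of 3 rose, AT1G13370 by 2.47-fold (SE 0.41 on the log2 scale), with a camera adjusted p of 0.562 and an adjusted p of 0.802 with an estimated correlation. Its call ended with median centring (0.96), low values raised (1.27) and the pseudocount (1.05), by the unmoderated two-sample test (adjusted p = 0.0860), without blue light replicates 1 and 2 (1.04) or 3 and 4 (1.16), and without white light replicates 3 and 4 (1.22) or 7 and 8 (adjusted p = 0.0648). The log2 change of AT1G13370 was 2.44 without normalization. None of the 3 tested members of the NDH complex list passed (camera adjusted p = 0.943, and adjusted p = 0.945 with an estimated correlation).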
